A study of Homo sapiens with 12 samples.

How the data were processed

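Gene expression was measured on 12 one-colour microarrays (Affymetrix Human Genome U133 Plus 2.0) in human embryonic stem (hES) cells of the established lines SA01 and VUB01 and in mesenchymal stem cells (MSC) derived from each line, with 3 biological replicates per group. Per the labels, the hES cells grew on inactivated mouse fibroblasts, the MSC came from hES cells replated on gelatin in serum, and RNA was amplified in a pair of labelling rounds. The submitters' processing notes name GCRMA, a method that corrects background from probe sequence and summarises probes, and the version is not given in the sources used here. The deposited values are intensity summaries on a linear scale, 1 per probe set and array, with a group mean of the array medians between 7.95 and 8.23 and no missing or negative value. Their log2 was taken here before every step, although a deposited log2 scale had been assumed before the data were examined.

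Of 54675 probe sets, 41097 list 1 gene symbol in the probe table, 1801 list several and 11777 are not in it, among them the 62 manufacturer controls. Probe sets of several symbols were used only where every probe set was tested as its own feature, so POU5F1, whose probe set lists several genes, has no value. The 99 probe sets of chromosome Y and X-inactivation genes were left out of every fit. A probe set was kept when its log2 intensity was above 4 on at least 3 of the 12 arrays. Each gene was represented by its kept probe set with the highest mean over all arrays, which gave 11573 genes, 5239 of them with more than 1 kept probe set. For 8165 genes no probe set passed the filter. The files used here hold no detection calls, so a value under 4 is described as under the filter and not as absent. Where every array of a group lay under 4, values under 4 were set to 4 and the fold is given as a lower bound. Where only some arrays of a group lay under 4, the fold is also given with values under 4 set to 4, and the text says so.

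One linear model with a mean per group was fitted to all genes in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold. The comparisons were MSC against hES averaged over the lines, the same in each line, the difference of these changes between the lines (the interaction), and SA01 against VUB01 among hES and among MSC. The 36 gene lists were fixed before the data were examined, as were the comparisons, the filter, the call and the alternatives not named as added. The 35 lists with at least 5 measured members were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists of a comparison, then with an estimated correlation and with fry. Members were counted as called over all genes and, separately, adjusted over the list alone. Adjusted p values of single genes are limma's and those of lists are camera's.

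Genes were named by a rule fixed with the lists. For MSC against hES it takes the 6 largest rises and falls called in both lines, up to 3 called genes per list, and NANOG, SOX2, POU5F1, NT5E, THY1, ENG, PTPRC and CD34 as identity checks. For the interaction and for each comparison between lines it takes the 8 largest changes each way and up to 2 called genes per list. Members that moved against the rest of their list, surface markers and keratins already expressed in hES cells, further called HOX, matrix and transition genes, and genes called in both cell states were named after their values were seen. Of the genes named, 1 probe set changed in the opposite direction for PDGFRA, SDC1 and FLT1.

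Tested on simulated data of 11573 genes with the same groups, the model called 83% of genes shifted by a log2 of 1.5 and 100% of genes shifted by 3 for MSC against hES. It called 60% and 93% for the hES lines, and 35% and 74% for the interaction. False calls among 11373 unchanged genes numbered 1, 3 and 7. The simulation drew independent normal noise for each gene, with 1 spread shared by all groups and 200 genes changed. The real arrays differed in residual SD, from 0.253 to 0.629, and more genes changed, so these rates may not carry over. The number of arrays, 3 per group, limits the precision of every comparison.

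Replicate numbers were checked for pairing from the correlation of residuals. Only between SA01 and VUB01 hES were all same-number correlations above 0.1 (0.188, 0.240 and 0.436), so a fit with replicate number as a block is given beside that comparison. Alternatives were a missing or stricter filter, values under 4 set to 4, no fold minimum, an adjusted p under 0.01, a trended robust prior, quantile normalization again, median centring, other choices of probe set, a replicate block, only the 6 arrays compared, and leaving out each array. The mean of the poly-A labelling controls as a covariate was added after the data were seen. Chromosomes and gene order came from a RefSeq table of GRCh38.p14. GC content of the genes was not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.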

Results

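The series compared undifferentiated hES cells with MSC derived from them, in lines SA01 and VUB01, to describe how gene expression differs between the states. Each of the 4 groups, SA01 hES, VUB01 hES, SA01 MSC and VUB01 MSC, held 3 arrays. Between 20702 and 21816 probe sets per array lay above the filter, which was 39.1% ± 0.771 (SD, n = 3) in SA01 hES, 39.2% ± 0.170 in VUB01 hES, 38.3% ± 0.245 in SA01 MSC and 38.1% ± 0.151 in VUB01 MSC. The correlation across genes between arrays of the same group was 0.928 to 0.981, between the lines within a state 0.899 to 0.969, and between hES and MSC arrays 0.642 to 0.749. The difference between the 3' and 5' probe sets of GAPDH, a sign of RNA quality, moved with the state, at 1.06 ± 0.04 and 0.99 ± 0.05 in SA01 and VUB01 hES and 0.59 ± 0.16 and 0.63 ± 0.13 in the MSC (log2). The 28S control did so too, at 11.81 ± 0.35 and 11.55 ± 0.72 in hES and 10.74 ± 0.04 and 10.39 ± 0.31 in the MSC. The poly-A labelling and hybridization controls also had higher means in hES of both lines. The poly-A means were 9.32 ± 0.49 and 8.83 ± 0.95 in SA01 and VUB01 hES. In the MSC they were 8.01 ± 0.05 and 8.39 ± 0.13. The hybridization means were 11.44 ± 0.27 and 11.18 ± 0.10 in hES and 11.01 ± 0.16 and 10.93 ± 0.10 in MSC. MSC against hES was not fitted with the poly-A covariate. The actin and 18S controls did not follow the state. The 3' and 5' difference of actin was 3.39 ± 0.30 and 3.89 ± 0.58 in SA01 and VUB01 hES. In the MSC it was 3.62 ± 0.24 and 3.65 ± 0.29. The 18S control was higher in SA01, at 13.93 ± 0.32 in hES and 14.01 ± 0.05 in MSC, against 13.30 ± 0.49 and 13.16 ± 0.15 in VUB01. The first principal component, which parted hES from MSC, held 75.8% of the variance. Values below are mean log2 intensities ± SD of 3 arrays, and fold changes come from the fitted group means.

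The genes that maintain pluripotency fell in the MSC of both lines, NANOG and SOX2 to under the filter. All 27 measured pluripotency genes fell (camera adjusted p = 1.00e-10, and 0.00758 with an estimated correlation). NANOG, a core transcription factor of the pluripotent state, went from 12.37 ± 0.51 in SA01 hES and 12.80 ± 0.32 in VUB01 hES to 2.37 ± 0.03 and 2.39 ± 0.03 in the MSC, at least 385-fold lower (limma adjusted p = 1.28e-11). SOX2, its partner, fell at least 363-fold (adjusted p = 1.92e-12). Other genes among the 6 with the largest fitted falls were L1TD1, at least 982-fold, LIN28A, which blocks maturation of let-7 microRNAs, at least 1004-fold, and TRIM71, at least 882-fold. SLC7A3, a transporter of cationic amino acids, fell at least 282-fold.

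Most epithelial genes fell with them, though not all. Of 28 junction and adhesion genes, 21 fell and 1, the desmosomal DSP, rose (camera adjusted p = 1.06e-05, and 0.0107 with an estimated correlation). E-cadherin, CDH1, fell from 13.29 ± 0.14 and 12.97 ± 0.23 in SA01 and VUB01 hES to 2.40 ± 0.22 and 2.12 ± 0.01 in the MSC, at least 561-fold (adjusted p = 7.32e-13). ESRP1, which directs epithelial splicing, fell at least 163-fold. EPCAM, an epithelial adhesion molecule, fell 759-fold with values under 4 set to 4 (adjusted p = 1.04e-10). The keratin KRT8 went from 10.16 ± 0.35 to 12.63 ± 0.59 in SA01, and from 9.41 ± 0.19 to 8.63 ± 1.58 in VUB01.

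**Figure D1:**
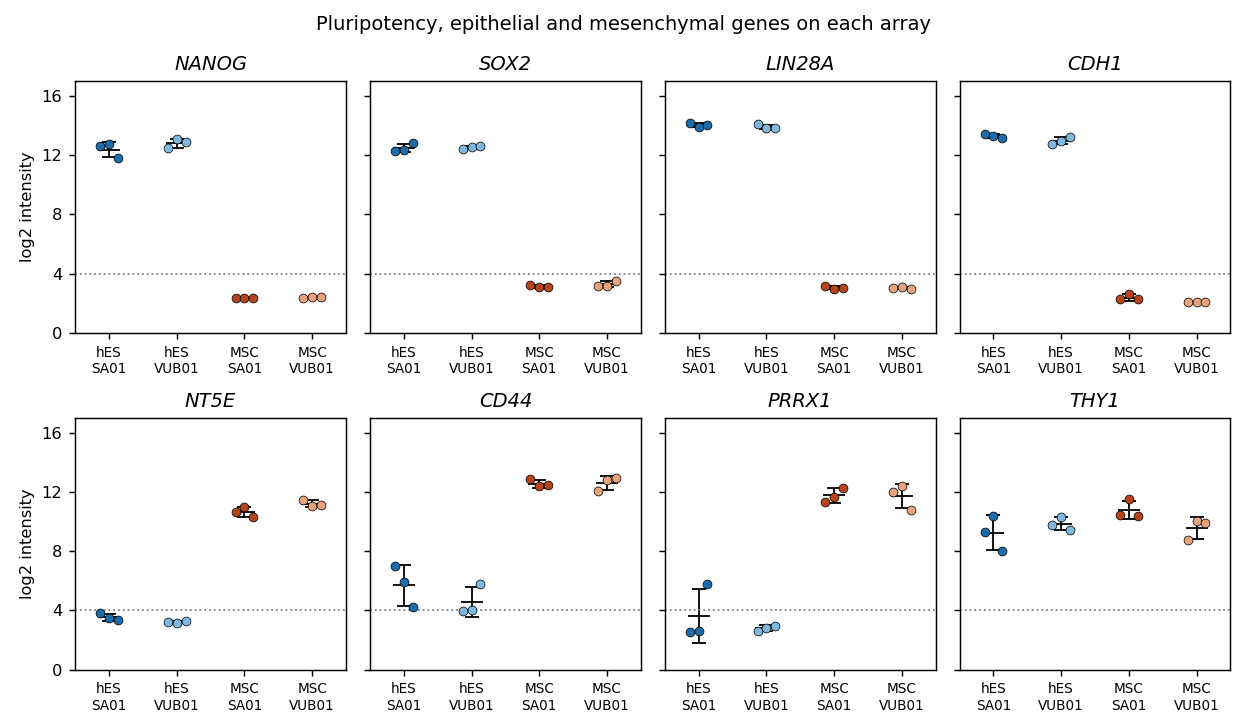
Log2 intensity of 8 genes on each of the 12 arrays (points), with the mean and SD of 3 arrays per group and a dotted line at the filter level of 4. NANOG, SOX2, LIN28A and CDH1 lie under 4 in all MSC arrays, NT5E lies under 4 in all hES arrays, and THY1 lies well above 4 in every group.

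Mesenchymal surface markers rose, and several were already expressed in hES cells. Of 20 measured members 17 rose and 1, the tetraspanin CD9, fell (camera adjusted p = 1.09e-07, and 0.00644 with an estimated correlation). NT5E, the ectonucleotidase CD73, rose at least 120-fold, from 3.54 ± 0.24 and 3.20 ± 0.07 in SA01 and VUB01 hES to 10.62 ± 0.34 and 11.20 ± 0.23 in the MSC (adjusted p = 3.76e-11). The hyaluronan receptor CD44 rose 171-fold with values under 4 set to 4, the collagen-binding integrin ITGA11 at least 15.6-fold, and ENG, CD105, at least 5.34-fold. THY1, CD90, was not called: its mean was 9.24 ± 1.18 and 9.84 ± 0.44 in hES and 10.77 ± 0.63 and 9.58 ± 0.72 in MSC of SA01 and VUB01 (adjusted p = 0.184). The integrin ITGB1, the tetraspanin CD63 and ALCAM were also well above the filter in hES cells, at 13.51, 12.54 and 10.09 in SA01 and 12.86, 12.53 and 8.97 in VUB01. Blood cell markers were near the bottom of the scale in all groups: 18 of the 19 with a probe set did not pass the filter, the 5 probe sets of PTPRC, CD45, exceeded 4 on 1 array (4.08), and the probe set of CD34 reached at most 2.06. The remaining blood marker, HLA-DRB1, fell at least 2.34-fold, and this list was too small to test.

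The matrix program of connective tissue came on in its place. Of 39 genes of collagens and extracellular matrix 33 rose and none fell, 34 when adjusted over the list alone (camera adjusted p = 3.51e-14, and 0.0353 with an estimated correlation). LOX, which cross-links collagen, rose at least 596-fold to 14.44 ± 0.49 in SA01 and 13.94 ± 0.38 in VUB01 MSC (adjusted p = 8.34e-08). COL8A1, a short-chain collagen, rose 392-fold with values under 4 set to 4, and the matricellular POSTN rose at least 169-fold. COL1A1 was already at 12.20 ± 0.46 in SA01 hES and 9.47 ± 1.04 in VUB01 hES, and reached 14.63 ± 0.16 and 14.79 ± 0.06 in the MSC. Of 19 matrix proteases and inhibitors 16 rose and MMP9 fell (camera adjusted p = 3.59e-07, and 0.00644 with an estimated correlation), led by the collagenase MMP1, at least 170.5-fold, and by TIMP3 and ADAM12. Other genes among the 6 largest rises were SRGN, a proteoglycan core protein, at least 360-fold, the BMP antagonist GREM1, at least 499.9-fold, IGFBP7, 544-fold with values under 4 set to 4, and NNMT, an enzyme of nicotinamide metabolism, at least 409-fold.

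Transcription factors and effectors of the mesenchymal state rose as well. Of 19 transition regulators 17 rose and none fell (camera adjusted p = 1.09e-07, and 0.0356 with an estimated correlation). PRRX1, a factor of limb and craniofacial mesenchyme, rose at least 174-fold to 11.76 ± 0.48 and 11.72 ± 0.84 in SA01 and VUB01 MSC. SNAI2, a repressor of E-cadherin, rose at least 70.8-fold, and FOXC2 62.2-fold. Of 27 genes of the actin cytoskeleton and focal adhesion 22 rose and none fell (camera adjusted p = 1.52e-10, and 0.0353 with an estimated correlation), with TGFB1I1, a focal adhesion scaffold, ANXA1 and CAV2 at the top. Smooth muscle and pericyte markers went the same way, with 13 of 16 higher and none lower (camera adjusted p = 1.74e-06, but adjusted p = 0.194 with an estimated correlation). Smooth muscle actins ACTA2 and ACTG2 rose 119-fold and 95.8-fold.

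**Figure D2:**
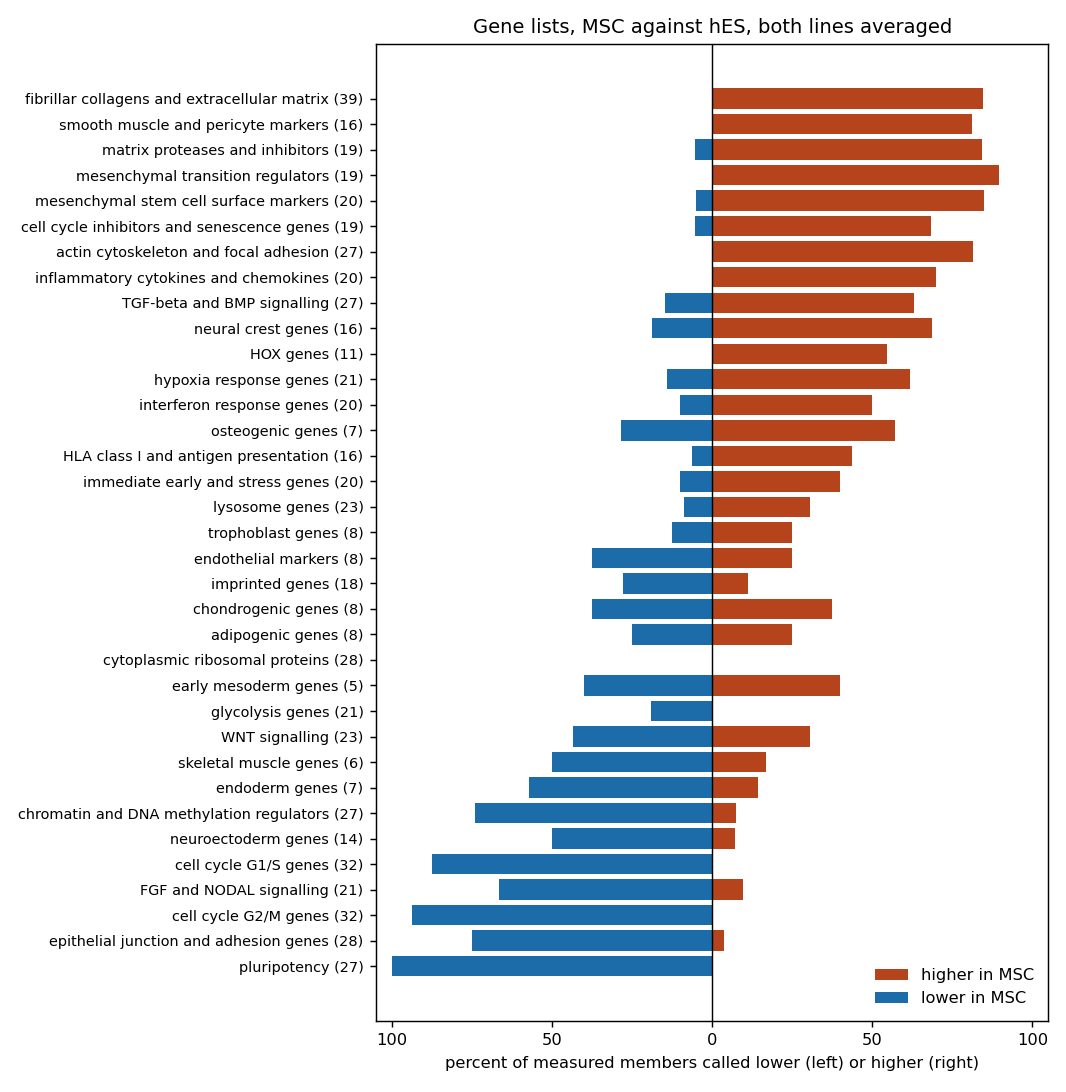
Percent of the measured members of each gene list called higher (right) or lower (left) in MSC than in hES, both lines averaged, with the number measured in brackets. All 27 pluripotency genes fell, 33 of 39 matrix genes rose, and no ribosomal protein gene was called.

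Markers of differentiated lineages did not move as blocks. Among osteogenic genes 4 of 7 rose and 2 fell (camera adjusted p = 0.134). RUNX2, the master factor of bone, rose at least 13.1-fold, whereas SPP1, osteopontin, fell by 2.67 on the log2 scale. Chondrogenic genes went both ways, 3 up and 3 down of 8 (camera adjusted p = 0.937), with COL11A1 43.8-fold higher and COL9A3 at least 21.8-fold lower. Adipogenic genes did so too, 2 up and 2 down of 8 (camera adjusted p = 0.938), CEBPD rising by 2.81 on the log2 scale (4.70 in SA01, and 0.92 and not called in VUB01, interaction adjusted p = 0.0505) and ZNF423 falling 10.4-fold. Among skeletal muscle genes 1 of 6 rose, MEF2C, and 3 fell, TNNT1 and ACTA1 the most (camera adjusted p = 0.938). In the trophoblast list 2 of 8 rose, PSG5 and SDC1, and TFAP2C fell (camera adjusted p = 0.249). PSG5 passed the filter only in VUB01 MSC, at 4.19, 6.50 and 10.03, and lay under it on all SA01 MSC arrays (interaction adjusted p = 0.169). In the endothelial list 2 of 8 rose, FLI1 and ENG, and 3 fell, among them the VEGF receptor KDR, 14.7-fold (camera adjusted p = 0.645).

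Genes of early embryonic lineages and of body position went different ways by list. Of 14 neuroectoderm genes 7 fell, led by OTX2, at least 160-fold, and ZIC2, and 1, STMN2, rose (camera adjusted p = 0.0519). Of 7 endoderm genes 4 fell, including CXCR4 and EOMES, and GATA6 rose (camera adjusted p = 0.684). The endoderm count rested on single cultures, with 1 gene lower without SA01 hES replicate 3 or VUB01 hES replicate 3, whose list means of 8.26 and 7.26 were the highest, while the lowest hES mean, 3.24, lay under every MSC array. Early mesoderm genes split, with GATA2 and PDGFRA among the 2 that rose of 5, and KDR among the 2 that fell (camera adjusted p = 0.937). Of 16 neural crest genes 11 rose and 3 fell (camera adjusted p = 0.00539, but adjusted p = 0.2 with an estimated correlation). The forebrain and branchial arch factor DLX1 rose at least 55.0-fold, while the neuregulin receptor ERBB3 fell at least 48.8-fold. HOX genes, which set position along the body axis, rose in 6 of 11 cases with none lower (camera adjusted p = 0.00141, but adjusted p = 0.2 with an estimated correlation), with HOXB3 and HOXB2 at least 10.8-fold and 5.40-fold higher.

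Most FGF and NODAL genes fell, and most TGF-beta and BMP genes rose. Of 21 FGF and NODAL genes 14 fell, LEFTY1 by at least 95.8-fold, and 2, INHBA and ETV5, rose (camera adjusted p = 0.0078, but adjusted p = 0.0752 with an estimated correlation). INHBA encodes the activin A subunit and rose 121-fold. Of 27 TGF-beta and BMP genes 17 rose and 4 fell (camera adjusted p = 5.84e-05, but adjusted p = 0.194 with an estimated correlation). The ligand TGFB2 rose at least 124-fold, and TGFBI, a matrix protein induced by TGF-beta, 138-fold. WNT genes split, 7 up and 10 down of 23 (camera adjusted p = 0.938): the receptor FZD5 fell at least 392-fold and SFRP2 at least 154-fold, and WNT5A rose 46.2-fold.

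Proliferation genes were lower in MSC and inhibitors of the cycle higher. Of 32 G1/S genes 28 fell (camera adjusted p = 9.32e-05, but adjusted p = 0.53 with an estimated correlation), with the origin protein ORC1, CDC25A and MCM5 falling most. Of 32 G2/M genes 30 fell (camera adjusted p = 0.000708, but adjusted p = 0.659 with an estimated correlation), and BUB1, a kinase of the spindle checkpoint, fell 24.7-fold with values under 4 set to 4. The G2/M list differed widely between MSC cultures: its mean per array was 5.32, 9.83 and 7.89 in VUB01 MSC replicates 1, 2 and 3 and 7.53, 6.99 and 7.27 in SA01 MSC, against 10.22 to 10.68 in the 6 hES arrays. Of 19 cell cycle inhibitors and senescence genes 13 rose and CDKN1C fell (camera adjusted p = 3.73e-06, but adjusted p = 0.0686 with an estimated correlation). CDKN2B, the inhibitor p15, rose at least 58.0-fold, to 10.83 ± 1.10 in SA01 and 8.89 ± 0.57 in VUB01 MSC.

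Of 27 chromatin and DNA methylation regulators 20 fell and 2, TET2 and HMGA2, rose (camera adjusted p = 0.000178, but adjusted p = 0.126 with an estimated correlation). The de novo DNA methyltransferase DNMT3B fell 228-fold, the DNA hydroxylase TET1 43.1-fold and the polycomb cofactor JARID2 28.1-fold. Imprinted genes split, 2 up and 5 down of 18 (camera adjusted p = 0.641), with PLAGL1 and PHLDA2 the ones that rose, and without 1 array 2 to 4 rose and 3 to 6 fell.

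Of 20 inflammatory cytokines and chemokines 14 rose and none fell (camera adjusted p = 3.8e-05, but adjusted p = 0.214 with an estimated correlation), with the pentraxin PTX3 153-fold higher and CXCL8 and PTGS2 at least 19.1-fold and 9.67-fold higher. Of 20 interferon response genes 10 rose and 2, BST2 and IFITM1, fell (camera adjusted p = 0.00109, but adjusted p = 0.142 with an estimated correlation). GBP1 rose at least 35.4-fold and SP100 at least 26.9-fold. Of 16 genes of HLA class I and antigen presentation 7 rose and PSMB8 fell (camera adjusted p = 0.00238, but adjusted p = 0.294 with an estimated correlation), and B2M, the class I light chain, rose 6.87-fold.

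Among metabolic and stress lists, 13 of 21 hypoxia response genes rose and 3 fell (camera adjusted p = 0.000677, but adjusted p = 0.126 with an estimated correlation), EPAS1, the factor HIF-2 alpha, rising 74.7-fold with values under 4 set to 4. Lysosome genes rose in 7 of 23 cases and fell in 2, NPC2 and GUSB (camera adjusted p = 0.00238, but adjusted p = 0.326 with an estimated correlation), with the protease CTSB 14.2-fold higher. Immediate early and stress genes rose in 8 of 20 cases and fell in 2, FOS and IER2 (camera adjusted p = 0.025, but adjusted p = 0.327 with an estimated correlation), IER3 rising 26.6-fold. Glycolysis genes fell in 4 of 21 cases with none higher (camera adjusted p = 0.641), the neuronal-type glucose transporter SLC2A3 falling 11.4-fold. No ribosomal protein gene of 28 was called, although the list lay lower in MSC than other genes (camera adjusted p = 0.0429, but adjusted p = 0.699 with an estimated correlation).

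In all, 2098 genes were higher and 3509 lower in MSC, 48.4% of the 11573 tested, and 2567 of them changed at least 4-fold. The median log2 change of all genes was -0.31, and the split depended on scaling: 2452 rose and 3025 fell after quantile normalization, 2690 and 2683 after centring each array on its median, with the direction of each list that passed camera kept, and the ribosomal list alone no longer called, at a camera adjusted p of 0.0652 and 0.798. Of the 106 results named by the rule for this comparison 5 lost their call under an alternative: PDGFRA, EOMES, GATA6, PSG5 and SDC1. Of the list members named beside them, after their values were seen, MMP9, CDKN1C, NPC2, GUSB and HMGA2 lost theirs without some single array.

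Each line gave a change of similar size and content. In SA01 1967 genes rose and 3357 fell, and in VUB01 2021 and 3446. Both lines shared 1512 risen and 2707 fallen genes, where 343 and 1000 would be shared if the lines were independent, and 7 genes went in opposite directions. Across genes, which are not independent replicates, the log2 changes of the lines correlated with r = 0.898 and rho = 0.883. Pluripotency genes fell in 26 of 27 cases in SA01 (camera adjusted p = 3.18e-12, and 0.0049 with an estimated correlation) and 25 in VUB01 (camera adjusted p = 4.05e-12, and 0.0046 with an estimated correlation), and in all 27 in each line when adjusted over the list alone. Matrix genes rose in 34 of 39 cases in SA01 (camera adjusted p = 7.95e-15, and 0.0368 with an estimated correlation) and 29 in VUB01, where 1 fell (camera adjusted p = 1.34e-13, and 0.0332 with an estimated correlation), 34 and 31 when adjusted over the list alone.

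**Figure D3:**
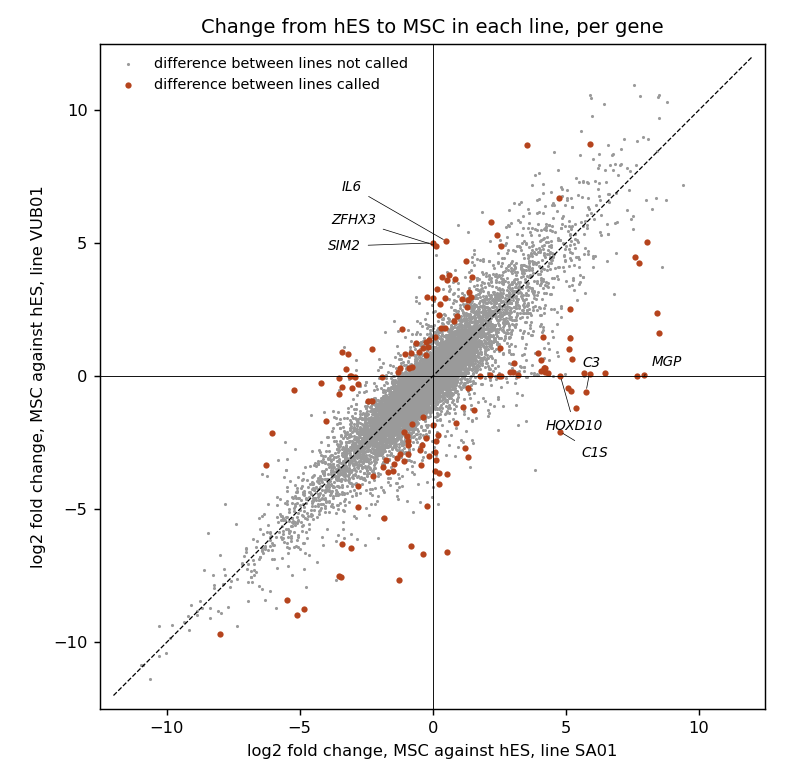
Log2 fold change from hES to MSC of each of the 11573 genes, in line SA01 (x axis) and line VUB01 (y axis), with equal change on the dashed line. The 154 genes whose change differed between the lines are in red, and 7 of the genes called in both lines went in opposite directions.

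The interaction asked which genes changed differently in the lines. It called 154 genes, 89 with a more positive change in SA01 and 65 with a more positive change in VUB01, of which 46 were called in the same direction in both lines. MGP, an inhibitor of calcification, was at 10.28 ± 2.28 in SA01 MSC and under the filter in the other groups, so that the changes differed at least 77.7-fold (adjusted p = 0.00915). TDO2, which degrades tryptophan, and the complement gene C3 had the same profile, at least 64.6-fold and 27.7-fold. C1S, another complement gene, was already at 6.11 and 6.83 in SA01 and VUB01 hES, rose to 10.90 in SA01 MSC and was at 4.75 in VUB01 MSC, a 116-fold difference of the changes. DIO2, which activates thyroid hormone, was under the filter in hES cells and above it on all SA01 MSC arrays and on 2 VUB01 MSC arrays, at 4.86 and 5.28. The proteoglycan DCN and the tight junction gene CLDN11, already above the filter in SA01 hES, differed 88.4-fold and 67.1-fold with values under 4 set to 4. SELENOP, a selenium carrier, differed at least 53.4-fold, since it was expressed in both hES groups, at 10.01 and 9.20 in SA01 and VUB01, and lay under the filter in VUB01 MSC. In the other direction SIM2, a neural transcription factor, reached 7.13 ± 0.53 in VUB01 MSC and lay under the filter in the other groups, at least 8.74-fold (adjusted p = 0.000137). The cytokine IL6 was at 7.36 ± 1.03 in VUB01 MSC and under the filter elsewhere, at least 10.3-fold (adjusted p = 0.00852).

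Camera called 6 lists in the interaction, and with an estimated correlation none was called. HOX genes changed more in SA01, with HOXD10, at least 11.1-fold, and HOXC10, at least 1.48-fold and so not shown to pass 2-fold, called of 11, 6 when adjusted over the list alone (camera adjusted p = 5.68e-05, but adjusted p = 0.488 with an estimated correlation). Transition regulators changed more in VUB01, with ZEB2 and VIM called of 19, 3 when adjusted over the list alone (camera adjusted p = 0.00526, but adjusted p = 0.554 with an estimated correlation). For both of these genes the hES cells differed more than the MSC: VIM was at 13.50 ± 0.37 in SA01 hES and 11.83 ± 0.47 in VUB01 hES, and at 14.85 ± 0.03 and 15.01 ± 0.04 in the MSC. Without SA01 hES replicate 2 the transition regulators called were 4, but without any of 8 other arrays, 2 in each group, only 1, and without VUB01 MSC replicate 3 the HOX genes called were 5. Of the 32 named interaction genes 21 lost their call under an alternative, and leaving out 1 array gave between 56 and 209 genes, lowest without SA01 MSC replicate 3 and highest without SA01 MSC replicate 1. The count fell to 60 with replicate number within each line as a block.

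The hES lines were compared to see how the starting cells differ. The largest single difference was the imprinted gene PEG3, at 11.51 ± 0.46 in VUB01 hES and 2.22 ± 0.02 in SA01 hES, at least 182-fold (adjusted p = 0.000246), together with its antisense transcript PEG3-AS1. NAP1L5, another imprinted gene, went the opposite way, at 8.62 ± 0.45 in SA01 hES and 3.51 ± 0.52 in VUB01 hES (at least 24.6-fold, adjusted p = 8.84e-05). Catalase, CAT, and the mitochondrial cochaperone DNAJC15 were higher in SA01 by log2 3.92 and 4.96 with values under 4 set to 4, with VUB01 values that ranged widely (SD 2.04 and 2.55). NR2F1, an orphan nuclear receptor of neural crest and forebrain, was higher in SA01 by 5.69 with values under 4 set to 4 (adjusted p = 0.0033), and so was the HOX cofactor MEIS1, by 4.02 with values under 4 set to 4. Among pluripotency genes 1 of 27 differed, GDF3, lower in SA01 by a log2 of -2.06.

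Mesenchymal genes tended to be higher in SA01 hES than in VUB01 hES, but unevenly across the cultures. Among 39 matrix genes COL1A1, COL1A2 and P4HA2 were higher and none lower, 8 when adjusted over the list alone (camera adjusted p = 9.47e-11, but adjusted p = 0.07 with an estimated correlation). Among 19 transition regulators ZEB1, ZEB2, TWIST1 and VIM were higher, 7 when adjusted over the list alone (camera adjusted p = 1.39e-07, but adjusted p = 0.0597 with an estimated correlation). The matrix list averaged 8.32, 7.19 and 8.21 on SA01 hES replicates 1, 2 and 3 and 6.32 to 6.94 on the VUB01 hES arrays, and POSTN was at 9.24, 2.87 and 8.85 and SNAI2 at 7.39, 3.36 and 8.99 on the SA01 arrays. Without SA01 hES replicate 2 the matrix genes called were 11, without SA01 hES replicate 1 or VUB01 hES replicate 2 they were 0, and without SA01 MSC replicate 2 or 3, which enter the pooled spread, 1. Transition regulators called were 2 without SA01 hES replicate 1 or 3 or VUB01 hES replicate 2, and 5 at most without 1 array. ZEB1 was at 6.10 ± 1.04 in SA01 hES and 3.18 ± 0.78 in VUB01 hES, and ZEB2 at 6.65 ± 0.61 and 4.05 ± 0.24. Neural crest genes, with NR2F1 and TWIST1 called of 16 over all genes and over the list alone, and hypoxia genes, with none called of 21 over all genes and 8 when adjusted over the list alone, were also higher in SA01 as lists (camera adjusted p = 3.32e-06 and 1.66e-08, but adjusted p = 0.07 and 0.0581 with an estimated correlation). Lists of other lineages lay higher in SA01 hES too, early mesoderm at 8.22, 6.33 and 8.403 on replicates 1, 2 and 3 against 5.73 to 6.01 on the VUB01 arrays (camera adjusted p = 0.00871, but adjusted p = 0.177 with an estimated correlation), and the osteogenic, neuroectoderm and endoderm lists at camera adjusted p = 0.0257, 0.0133 and 0.0483 (but adjusted p = 0.148, 0.447 and 0.498 with an estimated correlation). Of these lists only COL1A1 was called over all genes, and 1 early mesoderm gene more when adjusted over the list alone. The poly-A labelling controls of the arrays, in log2, were 9.15, 9.87 and 8.94 in SA01 hES and 9.74, 8.91 and 7.83 in VUB01 hES.

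Genes of chromosome 20 were higher in VUB01 hES as a block. Their median SA01 minus VUB01 difference, over 332 genes, was -0.42 relative to all autosomal genes, with 78.6% of them below the autosomal median, while no other autosome exceeded 0.0658 in either direction (camera adjusted p = 1.01e-09, but adjusted p = 0.962 with an estimated correlation). The shift was carried by 2 of the 3 VUB01 hES arrays, 0.67 in replicate 1, 0.52 in replicate 2 and 0.01 in replicate 3. Among the MSC the same genes differed between the lines by a median of 0.04.

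**Figure D4:**
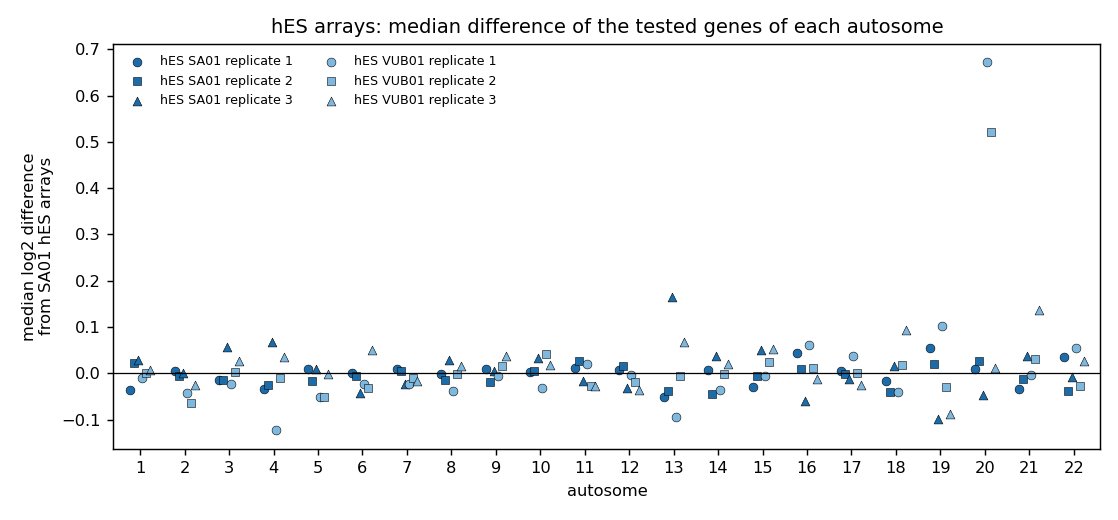
Median log2 difference of the tested genes of each autosome on each hES array from the mean of the SA01 hES arrays (for a SA01 array, from the other 2), relative to all autosomal genes. Replicates 1 and 2 of VUB01 hES lie at 0.67 and 0.52 for chromosome 20, and replicate 3 at 0.01.

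Camera called 15 lists between the hES lines, and none with an estimated correlation. In all, 78 genes were higher and 76 lower in SA01 hES than in VUB01 hES, and the balance depended on the processing: 96 and 53 after quantile normalization and 111 and 48 after median centring, but 74 and 97 with values under 4 set to 4, 48 and 75 without probe sets that may cross-hybridize, 174 and 260 with every probe set tested, and 47 and 73 without SA01 hES replicate 3. With replicate number as a block the total was 75, with only the 6 hES arrays it was 20, and leaving out 1 array gave 45 (without VUB01 hES replicate 2) to 207 (without SA01 hES replicate 2).

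The derived MSC of the lines differed in more genes than the hES cells they came from. They differed in 691 genes, 340 of them lower in SA01 MSC and the others higher. Control probe sets differed too, with the poly-A controls at 8.01 ± 0.05 in SA01 and 8.39 ± 0.13 in VUB01 MSC (log2). The 18S control was at 14.01 ± 0.05 in SA01 and 13.16 ± 0.15 in VUB01 MSC. VUB01 MSC replicate 1 stood apart, with the largest residual SD (0.629) and a score on principal component 3 of -68.7 against 34.2 and 19.7 in the other 2, and without it 822 genes differed and 14 G2/M genes were lower in SA01 MSC, against 0 with all arrays. The largest differences were CLDN11, at 12.16 ± 1.40 in SA01 and 3.24 ± 0.47 in VUB01 MSC (at least 286-fold, adjusted p = 8.17e-05), and the small proteoglycan DCN, at 12.32 ± 1.98 and 3.88 ± 0.04 (at least 321-fold, adjusted p = 0.000457). CAT and NAP1L5, higher in SA01 hES, were also higher in SA01 MSC, CAT at least 82.7-fold and NAP1L5 by log2 6.23 with values under 4 set to 4, and PEG3, under the filter in SA01 MSC as in SA01 hES, was at least 10.1-fold lower. SFRP1, a secreted WNT antagonist, was higher in SA01 MSC by log2 4.46 and BMP4 at least 10.3-fold higher. In VUB01 MSC, IL6 was at least 10.3-fold and SIM2 at least 8.74-fold higher, and with values under 4 set to 4 PNMA2 was 17.1-fold and the mucin-type glycosyltransferase GALNT3 17.9-fold higher.

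HOX genes were the list that differed most between the MSC. Of 11 measured genes 8 were higher in SA01 MSC and none lower, the same number when adjusted over the list alone (camera adjusted p = 1.12e-10, but adjusted p = 0.151 with an estimated correlation), and 4 were called without SA01 MSC replicate 2. HOXD10 was at least 11.1-fold higher in SA01 MSC, and HOXC6 was at 11.02 ± 0.73 in SA01 and 4.53 ± 3.17 in VUB01 MSC. The others called were HOXB5, HOXB6, HOXB7, HOXC4, HOXC8 and HOXC10, the last with a bound of 1.48-fold. Matrix genes were higher in SA01 MSC in 5 of 39 cases, DCN, FBLN5, PCOLCE, COL16A1 and FBLN1, and in 7 when adjusted over the list alone (camera adjusted p = 0.00657, but adjusted p = 0.522 with an estimated correlation), with 2 called without SA01 MSC replicate 2 or 3 or VUB01 MSC replicate 3. Lysosome genes were higher in 2 of 23 cases, CTSO and SGSH, on both counts (camera adjusted p = 3.26e-05, but adjusted p = 0.33 with an estimated correlation). Of 28 epithelial genes CDH3, KRT8, KRT18 and PKP2 were higher and MARVELD2 lower, in a list that camera did not call (adjusted p = 0.0596).

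**Figure D5:**
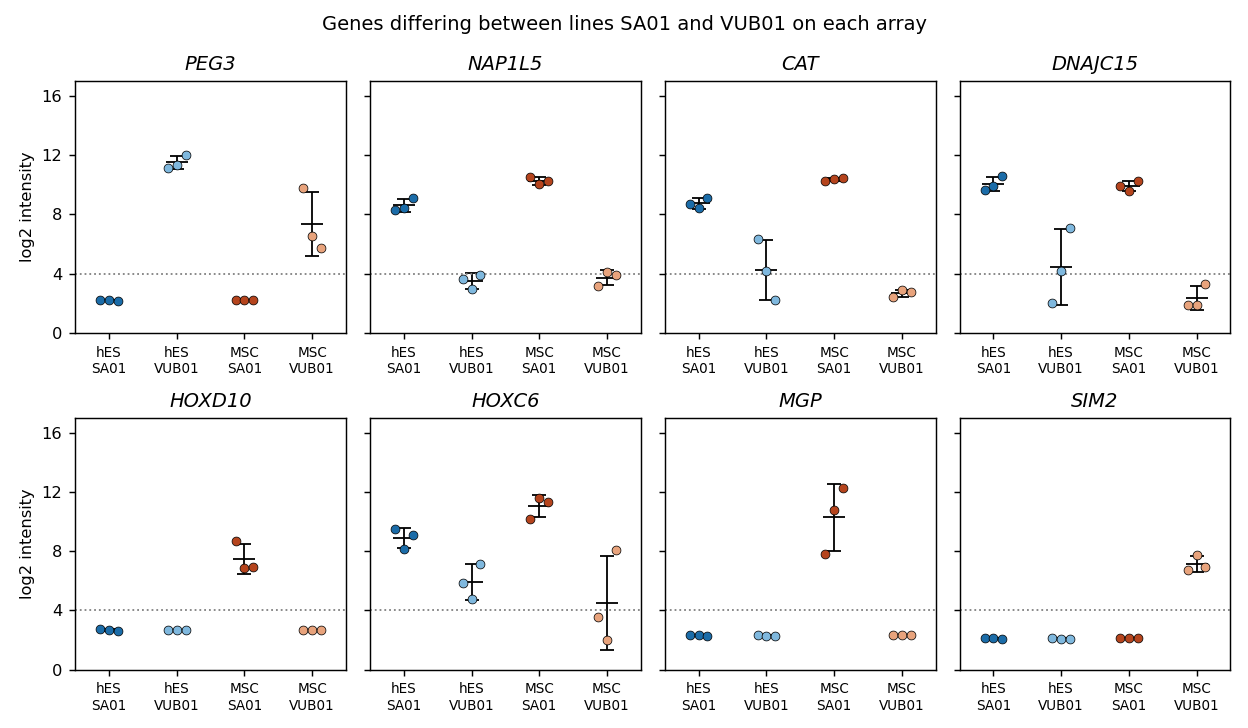
Log2 intensity of 8 genes that differed between lines SA01 and VUB01, on each of the 12 arrays (points), with the mean and SD of 3 arrays per group and a dotted line at the filter level of 4. PEG3 lies under 4 in all SA01 arrays of both states, and MGP and HOXD10 rise above 4 in SA01 MSC alone.

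Camera called 8 lists between the MSC, and none with an estimated correlation. Under other scalings SA01 MSC were higher in 415 and lower in 240 genes (quantile normalization) or 409 and 249 (median centring). Lower genes outnumbered higher ones, 639 to 413, with no fold minimum, 781 to 662 with every probe set tested, 302 to 264 without probe sets that may cross-hybridize and 444 to 378 without VUB01 MSC replicate 1. They did so too, 355 to 305, with the poly-A covariate, which was added after the data were seen. The total of 691 became 155 with only the 6 MSC arrays and 272 to 822 when 1 array was left out, falling to 272 without SA01 MSC replicate 2 and to 335 without SA01 MSC replicate 3.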

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

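The tests of the mesenchymal genes and of 1 discordant array behind the HOX difference were chosen only after the result was seen. What brought the results of this part here is the interaction: in each case the change from hES cells to MSC differed between lines SA01 and VUB01, and the value given is the SA01 change minus the VUB01 change in log2. Among 100 splits of the arrays between the lines within each state, 3 gave at least as many genes as the real split with its 154, the real one included. These splits also break up the line differences within each state, so they do not test the interaction alone. Chance as the source of that count is therefore not excluded by them. Pairing of the hES replicates by number was inferred from the residual correlations and is not certain. VUB01 replicate 1 with SA01 replicate 2 gave 0.218, more than the 0.188 of the replicates numbered 1. With replicate number within each line as a block the count was 60, of which 54 were among the 154. No splits were run for that model. That block pairs hES with MSC arrays of the same number, whose residual correlations, -0.120 to 0.080, gave no sign of pairing. It does not test the pairing of the hES replicates. The highest other split gave 546 genes, more than 3 times the real count. The splits with larger counts moved 2 hES arrays and all 6 MSC arrays. Exchanging all MSC arrays reverses the sign of their line difference. Such a split therefore adds the line differences of the states, that of hES in part, instead of subtracting them. It counts line differences, those among the MSC alone included, and not the interaction. Other splits that moved as many arrays gave 97 and 94.

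In brackets the fitted difference comes first and the difference with values under 4 set to 4 second, and only the second is a size where a group lay under the filter. The change was larger or more positive in SA01 for MGP (7.92, 6.28), TDO2 (7.66, 6.01), SELENOP (7.13, 5.74), DIO2 (6.87, 6.77), C1S (6.86, 6.86), CLDN11 (6.56, 6.07), TMT1A (6.36, 5.22), C3 (6.36, 4.79), DCN (6.36, 6.47), HOXD10 (4.77, 3.48), FBLN5 (4.59, 4.19), SFRP1 (4.20, 4.20), CDH3 (4.11, 3.95), CTSO (3.17, 2.36), PROM1 (2.95, 1.99), GBP2 (2.69, 2.74), HOXC10 (2.54, 0.57) and SALL4 (1.66, 0.46). It was more positive in VUB01 for ANXA1 (-5.16, -4.85), SIM2 (-5.01, -3.13), ZFHX3 (-4.80, -4.80), EPHB1 (-4.71, -3.21), IL6 (-4.56, -3.36), PNMA2 (-4.32, -3.90), OPCML (-4.002, -3.56), RNF5 (-3.94, -3.65), VEGFA (-3.39, -3.39), ZEB2 (-3.22, -3.17), COL1A1 (-2.89, -2.89), FLI1 (-1.96, -1.58), VIM (-1.82, -1.82) and ETS1 (-1.50, -1.50). Each of these 32 genes had a limma adjusted p under 0.05 with 3 arrays per group, in the fit without a replicate block. With that block 54 of the 154 interaction calls were kept. Under at least 1 of the alternatives, 21 of these 32 genes lost their call. With values under 4 set to 4, EPHB1, PROM1, CTSO, SALL4 and HOXC10 were no longer called, and for SALL4 and HOXC10 the difference was under 2-fold.

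As lists, camera called HOX genes (mean 1.68, adjusted p = 5.68e-05), adipogenic genes (1.52, adjusted p = 0.0172) and lysosome genes (0.60, adjusted p = 0.0172) as changing more upwards in SA01. Transition regulators (-1.13, adjusted p = 0.00526), neural crest genes (-1.23, adjusted p = 0.0196) and hypoxia genes (-0.69, adjusted p = 0.0205) changed more upwards in VUB01. With an estimated correlation the adjusted p was 0.488 for HOX and adipogenic genes, 0.642 for lysosome genes and 0.554 for the other 3 lists.

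The interaction of the transition regulators goes back to mesenchymal genes that were higher in SA01 hES than in VUB01 hES. The difference was uneven, as SA01 hES replicate 2 had the lowest matrix mean of the 3 SA01 hES arrays. Over the 97 measured members of 4 mesenchymal lists the mean difference was 0.99, with 82 members above 0, 8 called higher and 0 called lower. Labelling is argued against in part by a mean of 1.14 with the poly-A controls as a covariate. Within SA01 hES, however, replicate 2 had the highest poly-A level, 9.87 against 9.15 and 8.94 in replicates 1 and 3. The unevenness therefore went with the poly-A level, and labelling is not excluded. Cells like the derived SA01 MSC within the SA01 hES cultures cannot be told apart from other sources: 24 members abundant in SA01 MSC and low in VUB01 hES implied shares of such cells with a median of 1.02% and quartiles of 0.427% and 4.42%, which neither agree on 1 share nor exclude a small one. This test replaced an earlier one, by which 16 of the 24 lay under 25% of the level needed, because the level had been taken from members chosen for being called, and its thresholds were set with these values known. A lower share of undifferentiated cells cannot be told apart from other sources with these arrays, since the pluripotency mean was -0.30 with members going both ways and lists of other lineages, early mesoderm and endoderm among them, also lay higher in SA01 hES, and other differentiated cells, RNA of the mouse feeder cells and a difference between the lines themselves may also contribute and were not tested.

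The HOX difference between the MSC had a median of 2.33 over 11 genes. Another 17 of the 28 HOX genes with a probe set did not pass the filter. In 8 of the 11 every SA01 array lay above every VUB01 array, as in 9.70% of all tested genes. This count is no independent support. HOXD10, and any other gene above 4 in SA01 MSC alone, passed the filter through those arrays, which fixed its separation. A discordant array as the source of the whole difference is argued against, since the HOX median stayed between 2.04 and 2.76 without each of the 6 arrays. The number of calls leaned on 1 array, with 4 HOX genes called without SA01 MSC replicate 2 and 6 to 8 without any other. The cut of 4 set for that count was chosen after the result was seen and equals its lowest value, so the count decides nothing. As the source of a HOX difference of this size, fewer mesenchymal cells in the VUB01 MSC cultures are argued against as well. The 1512 genes higher in MSC in both lines had a median difference of -0.0250 (quartiles -0.45 and 0.43). They were chosen by calls in both lines on these same arrays, which favours values near 0, so a smaller shortfall of mesenchymal cells is not excluded. A candidate explanation that stays open is that the lines gave MSC of different positional identity, for which no test was made, and differences between derivations, which follow the lines here, are open too.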

How the results depend on the processing

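The poly-A covariate was chosen after seeing the data, and the other alternatives were planned. No gene named by the rule and none of the 52 lists called by camera changed direction under any alternative run. Lists that camera did not call were not followed. The balance of higher and lower genes did change, to 2690 and 2683 for MSC against hES after median centring and to 74 and 97 for the hES lines with values under 4 set to 4. Testing every probe set as its own feature gave 4425 higher and 6681 lower features for MSC against hES, 10523 in SA01, 10886 in VUB01, 343 in the interaction, 434 between the hES lines and 1443 between the MSC, since more features were tested. An adjusted p under 0.01 gave 46 for the interaction, 50 for the hES lines and 236 for the MSC, and no fold minimum gave 1052 for the MSC, as a stricter and a looser call must move a count. No filter gave 101 for the hES lines. Replicate number as a block gave 60, 75 and 451 for the interaction, hES lines and MSC. The block was within each line for the interaction and within each state for the others. Only the 6 arrays compared, with the spread taken from them alone, gave 20 for the hES lines and 155 for the MSC. The poly-A covariate gave 278 for the hES lines. The interaction has no fit with 6 arrays. With 6 arrays MSC against hES still gave 5364 in SA01 and 5213 in VUB01. For the missing filter, the block, the fits with 6 arrays and the covariate the cause was not tested. Without 1 array the counts were 2016 to 2162 higher and 3412 to 3556 lower for MSC against hES, 5023 to 5428 in SA01, 5078 to 5538 in VUB01, 56 to 209 for the interaction, 45 to 207 for the hES lines and 272 to 822 for the MSC. The interaction count moved most without SA01 hES replicate 1 (72), VUB01 hES replicate 2 (63) and replicate 1 (84), SA01 MSC replicate 2 (62) and replicate 3 (56). The hES count moved most without SA01 hES replicate 1 (51), VUB01 hES replicate 1 (94) and replicate 2 (45), and the MSC count without SA01 MSC replicate 2 (272) and replicate 3 (335). Of the genes named by the rule, 5 of 106 results for MSC against hES lost their call under some alternative, 21 of 32 for the interaction, 17 of 24 for the hES lines and 27 of 51 for the MSC. Of list members named beside them, MMP9, CDKN1C, NPC2, GUSB and HMGA2 lost their call for MSC against hES without some single array, P4HA2 and VIM for the hES lines, and COL16A1, FBLN1, PCOLCE, MARVELD2, PKP2, HOXB5, HOXB6, HOXC4 and HOXC10 for the MSC. Of 52 lists called by camera, 45 lost their call with an estimated correlation, and 7 kept it, 21 lost it with fry, and 6 lost it after quantile normalization and 6 after median centring, among them the ribosomal list for MSC against hES, the osteogenic and endoderm lists for the hES lines and the adipogenic, early mesoderm and WNT lists for the MSC. Genes near the filter are limited by signal over background, so the main fit left out 8165 genes, which the fit without a filter included.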

Other observations

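The tests of genes called in both states and of a chromosome 20 difference carried by both states were chosen only after the result was seen.

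Some differences between the lines held in both hES cells and MSC. Of the genes called between the lines, 29 were called in both states, all in the same direction, where 4.60 would be if the states were independent (exact binomial two-sided p = 3.73e-09 for the shared direction). That test takes genes as independent trials, which they are not, so its p measures no spread between lines or cultures. Named after their values were seen, they include the imprinted PEG3 (lower in SA01 at least 182-fold in hES and 10.1-fold in MSC) and NAP1L5 (higher at least 24.6-fold in hES), the zinc finger gene ZNF558 (lower at least 10.5-fold and 6.62-fold), and CAT and DNAJC15 (higher at least 82.7-fold and 59.8-fold in MSC). A difference carried by the line, in DNA sequence or methylation, is a candidate explanation for these 29, and neither was analysed here.

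Chance as the source of the counts for MSC against hES can be excluded, since 1 of 100 splits gave as many genes, the real one, with 2098 higher and 3509 lower against 976 at most in 1 direction in another split, and with 5607 in all against 1534. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05: 1 split, the real one, gave as many in line SA01 (5324, highest other 1), in line VUB01 (5467, highest other 0), between the hES lines (154, highest other 16) and between the MSC (691, highest other 8). Among the hES splits that part all replicate numbers as the real one does, the highest other was 0.

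Chromosome 20 genes were 1.34-fold higher in VUB01 hES than in SA01 hES by their median, -0.42 relative to all autosomes. Labelling, as read from the poly-A controls, is argued against in part, as the median was -0.52 with that covariate. On VUB01 hES replicates 1, 2 and 3 the poly-A level, at 9.74, 8.91 and 7.83, fell together with the shift. The SA01 hES arrays, at 9.15, 9.87 and 8.94, showed shifts of only 0.01, 0.03 and -0.05. Labelling is therefore not excluded. Expression level is argued against, as 0% of 10000 gene sets matched on expression gave a median as low. For the chromosome as a whole, a difference present in both states is argued against by the MSC median of 0.0371, which stayed between 0.02 and 0.06 without any 1 array. From ZCCHC3 to RALGAPA2, however, the MSC medians of the stretches were -0.15, -0.19 and -0.16, in the direction seen in hES. The other stretches lay between -0.04 and 0.19 in MSC, so a smaller difference in both states stays open for that part. All stretches of 30 neighbouring genes, 100% of 11, lay below the autosomes, and 6 of the 73 lower calls on autosomes lay on this chromosome, which holds 2.98% of the tested autosomal genes (Fisher exact two-sided p = 0.0213). An extra copy of most of chromosome 20 in the cultures behind VUB01 hES replicates 1 and 2, and not behind replicate 3 (0.67, 0.52 and 0.01), may explain the shift, which without replicate 1 was -0.28 and without replicate 3 was -0.58, but this was found and tested on the same data, GC content was not analysed here, and no measure of DNA copies was used.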
